A study of Gallus gallus with 12 samples.

How the data were processed

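The samples were microglia, the resident macrophages of the brain, sorted by FACS from the anterior hypothalamus of chicks (Gallus gallus), with 1 library for each pool of 10 to 12 birds. The labels cross 2 treatments. Heat conditioning consisted of 24 h at 39°C from day 3 after hatching, and controls were not conditioned. Saline or lipopolysaccharide (LPS, a bacterial cell wall component that activates innate immune cells) went into the third ventricle on day 10, and cells were taken 24 h later. This gave 4 groups of 3 libraries, 12 in all, with the group and replicate number of each library read from its labels. DNA methylation was also profiled in the study, per the labels, and is not analysed here.

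Per the labels' protocols, 15 ng of RNA entered bulk MARS-seq, a method that reads the 3′ ends of mRNA, and single reads of 100 bp were sequenced to about 25 M per sample. The submitters' processing notes name cutadapt, STAR, HTSeq, DESeq2 and the galGal5 genome build. Their versions, their order, the annotation release, the use of molecular identifiers and the strand setting of the counting are not given in the sources used here. Whether the counts are reads or collapsed molecules is therefore open, and so is the step at which most reads left the table. Counts of overlapping genes, antisense partners and near-identical copies are uncertain for the same reason.

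Raw counts per gene and library were deposited by the authors for 11207 genes, per the file headers. They were used unchanged in every test. The deposited table also holds a normalized signal (headed as normalized counts) for each gene and library. Each such value equals the raw count times a factor of its library, with no deviation above 0.01, and the factors ran from 1.13 to 6.25. How the authors set those factors is not stated, and the normalized signal served only to read the factors for an alternative scaling. Of the 11207 genes, 340 had no count in any of the 12 libraries. All value columns of the table were used.

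The table identifies genes by versioned Ensembl identifiers, and its name column repeats them. The reference list used, of 25635 chicken genes (assembly GRCg7b), gives an Ensembl identifier for 0 of them, so 0 of the 11207 identifiers could be matched to a symbol. The 35 gene lists and cell type marker lists that had been planned could for that reason not be applied, and no list was tested. No check of cell types, gene length or GC content was run either. Genes are given by identifier, at most 2 that rose and 2 that fell. The planned rule for naming took genes with an adjusted p under 0.05, a mean of at least 20 normalized reads and no overlap between the replicates of the compared groups, ranked by log2 fold change. It also asked for a symbol and for a fixed set of named genes to be followed, and those parts were dropped. Among genes that passed the rest of the rule, the 2 largest rises and the 2 largest falls with LPS in non-conditioned chicks are named. Their values are followed through all comparisons. Other genes are described by their values alone.

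Total counts ran from 189180 to 963146 per library, which is 0.757% to 3.85% of the 25 M reads stated in the labels. A floor of 3 counts per library corresponds to 3.11 to 15.9 CPM (counts scaled to the same total in each library) by the library's own total. The CPM of genes are relative to the counts of the tested genes, scaled by TMM. Intervals and floors from counts cover counting error only. Correlations of log2 CPM (prior count of 2) between replicates of a group ran from 0.884 to 0.956. A chi-square statistic of the counts of 2 replicates, divided by its degrees of freedom, ran from 2.02 to 9.75, more than the counting error of independent molecules. Since the counts may be reads, this does not by itself tell separate pools from technical duplicates. None was treated as a duplicate. The replicates are separate pools of birds as far as the labels say. The p-values of the main fit rest on a spread between pools estimated over all 4 groups, not over the compared pools alone.

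Tests were run in R 4.3.3. Genes were kept by filterByExpr on the groups with its minimum count of 10, which left 5170 genes. Library sizes were scaled by TMM. All 12 libraries entered one edgeR 4.0.16 quasi-likelihood fit (glmQLFit and glmQLFTest, 2-sided) with 1 mean per group and no covariate, so that the groups share an estimate of the spread. The comparisons were LPS against saline in non-conditioned chicks, LPS against saline in conditioned chicks, conditioning with saline, conditioning with LPS, and the interaction of both treatments. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The standard error of a log2 fold change is its size divided by the square root of the F statistic, and intervals have a confidence level of 95%. The effect of LPS with and without conditioning was compared by Fisher's exact test of the overlap of called genes, by rotation tests of each called set in the other pair of groups (fry in limma 3.58.1, with the signs of the first comparison, adjusted over the 2 tests) and by correlations across genes. Ratios of summed counts for genes near the floor have exact Poisson intervals. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

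The test was checked on simulated data, with counts drawn for the 5170 genes from the observed means, library sizes and dispersions, 200 genes changed per simulation and 5 simulations per comparison. For LPS in non-conditioned chicks, 8.8% of 1.5-fold, 44% of 2-fold, 82.8% of 4-fold and 93.2% of 8-fold changes were recovered, with 3.7% of the calls false. For LPS in conditioned chicks the shares were 10.8%, 45.6%, 87.2% and 93.2%, with 4.82% false. For conditioning with saline they were 8%, 37.2%, 88.8% and 92%, with 4.72% false. For conditioning with LPS they were 11.6%, 44.8%, 85.2% and 94.8%, with 6.78% false.

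The gene lists, the rule for naming, the 5 comparisons with their edgeR test, the correlations of the LPS effects and the following alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0 on all genes with its own filter, edgeR with RLE size factors, limma with quantile normalization, limma with library weights, no filter on low counts, a stricter filter of 20 counts in 3 libraries, a 2-fold minimum change, an adjusted p under 0.1, a fit on the compared libraries alone, the replicate number as a block, and each library left out in turn. The scaling by the authors' factors, the overlap and rotation tests of the called genes, and the effects averaged over conditioning or over injection were added after the data were seen. In addition, the called genes were counted for other splits of the libraries into groups of the same sizes, and libraries were thinned at random to the lowest total in 20 draws.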

Results

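Microglial transcriptomes were profiled in 12 libraries, 3 for each combination of heat conditioning and injection, 24 h after saline or LPS was given on day 10. Total counts were 315422, 189180 and 510210 in the saline non-conditioned libraries (replicates 1 to 3) and 589900, 236219 and 963146 in the saline conditioned libraries. In the LPS groups they were 317724, 615505 and 300739 without conditioning and 468415, 504861 and 451683 with it. Genes with at least 1 count numbered between 7698 and 9573 of 11207 per library, and the 10 most abundant genes held 12.1% to 19.8% of a library's counts. Replicates of the LPS conditioned group correlated at 0.948 to 0.956 in log2 CPM, and those of the saline non-conditioned group at 0.884 to 0.895. In a principal component analysis of log2 CPM, saline non-conditioned replicate 2, the shallowest library, lay apart on the first component (-41.0, with 17.1% of the variance). Saline non-conditioned replicate 3 lay apart on the second component (-36.9, with 16.8% of the variance). LPS non-conditioned replicate 1 lay apart on the third (-29.8, with 12.3%).

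**Figure D1:**
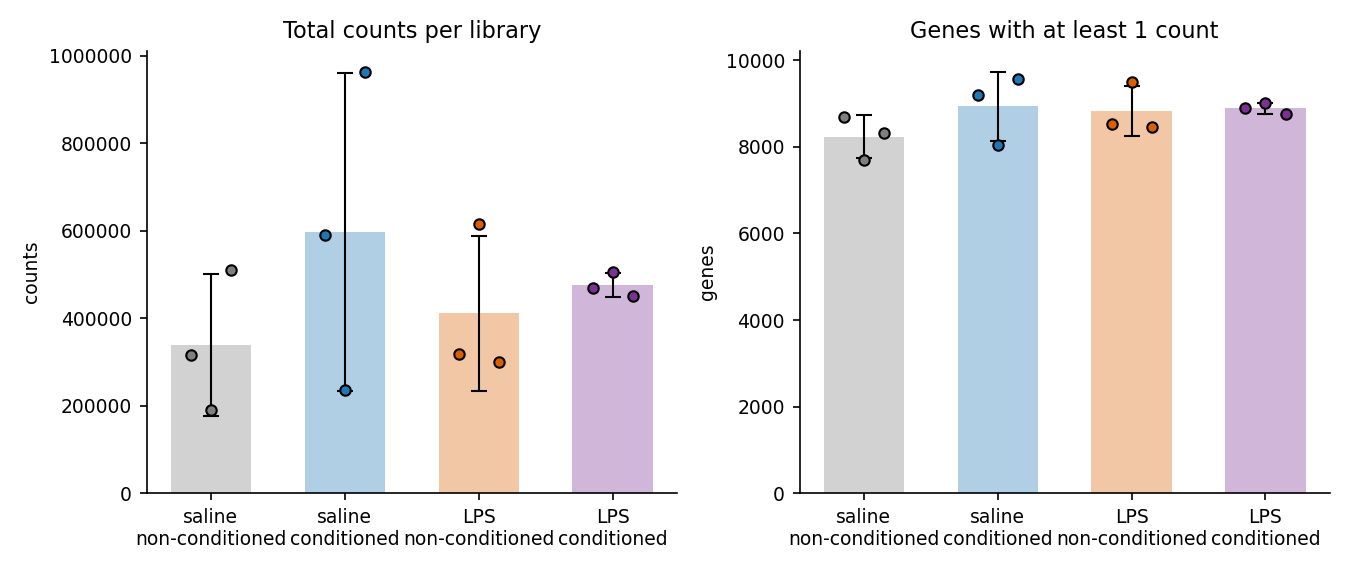
Total counts (left) and number of genes with at least 1 count (right) for each library of the 4 groups. Bars are group means, whiskers the SD and points the 3 libraries, and the totals span 189180 to 963146 counts.

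The first comparison asked how hypothalamic microglia of chicks without heat conditioning differed 24 h after LPS from those after saline. LPS raised 23 genes and lowered 5 of the 5170 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The 23 genes rose by a median log2 fold change of 1.66, within a range of 0.81 to 5.21, and the 5 genes that fell had log2 fold changes between -1.29 and -0.79. ENSGALG00000020316.5 rose from 13.1 ± 8.07 CPM with saline to 103 ± 8.66 CPM with LPS (SD, n = 3), a log2 fold change of 3.13 ± 0.38 (SE, edgeR adjusted p = 9.11e-05). Its saline libraries held 2, 4 and 5 counts, and it was called in 15 of 15 alternatives. Its level in each of the 3 LPS libraries lay above that in every saline library, which the rule for naming required. The largest rise was in ENSGALG00000010915.4, with a log2 fold change of 5.21 ± 1.09 (SE, edgeR adjusted p = 0.029). Its saline libraries held 1, 1 and 3 counts, at or under the floor of 3 counts per library, against 172, 31 and 6 counts with LPS. The ratio of summed counts per total was 34.4, with an exact Poisson interval of 14.5 to 107 that covers counting error only. Without LPS non-conditioned replicate 1 the log2 fold change was 2.82 and the call ended (edgeR adjusted p = 0.139), as it did without saline non-conditioned replicates 1, 2 and 3 (edgeR adjusted p = 0.0700, 0.118 and 0.146), where the log2 fold change was 4.94, 5.24 and 5.58, and with limma under quantile normalization and library weights (adjusted p = 0.513 and 0.624). Over its 14 alternatives the adjusted p ran from 8.59e-27, in edgeR with no filter on low counts, to 0.624. The next lowest was 0.00213, in edgeR without LPS non-conditioned replicate 3. The fit on the compared libraries alone gave no value for this gene.

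Among the genes that fell, ENSGALG00000024449.4 went from 112 ± 26.3 to 43.8 ± 6.38 CPM (SD, n = 3). This is a log2 fold change of -1.29 ± 0.27 (SE, edgeR adjusted p = 0.029). ENSGALG00000030994.1 went from 264 ± 61.0 to 138 ± 14.2 CPM (SD, n = 3), a log2 fold change of -0.93 ± 0.19 (SE, edgeR adjusted p = 0.029). In both genes each of the 3 saline libraries lay above every LPS library, a separation that the rule for naming required. The first call ended without saline non-conditioned replicate 2 and LPS non-conditioned replicates 2 and 3 (edgeR adjusted p = 0.136, 0.141 and 0.107), with limma under quantile normalization and with the compared libraries alone, over a range of 0.00714 to 0.141. The log2 fold change in these 5 settings was -1.11, -1.32, -1.19, -1.25 and -1.27. The second ended without saline non-conditioned replicates 2 and 3 and LPS non-conditioned replicates 2 and 3 (edgeR adjusted p = 0.136, 0.143, 0.187 and 0.0893) and in the same 2 other settings, over a range of 0.00471 to 0.187. Its log2 fold change there was -0.80, -0.84, -0.85, -0.90, -0.84 and -0.89. The count of 28 genes became 65 without saline non-conditioned replicate 1, 8 without saline non-conditioned replicate 2 and 12 without LPS non-conditioned replicate 2. A fit on the 6 compared libraries alone called 11 genes, all of them higher with LPS, and DESeq2 called 25 higher and 10 lower.

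The same question was asked of conditioned chicks, where LPS raised 6 genes and lowered 3 of 5170 (edgeR, adjusted p under 0.05). The 6 genes rose by log2 fold changes of 0.99 to 2.11. The largest of these rises was in a gene that went from 599.8 ± 68.0 CPM with saline to 2601 ± 1269 CPM with LPS (SD, n = 3). ENSGALG00000020316.5 rose from 17.3 ± 7.94 to 75.2 ± 6.81 CPM (SD, n = 3), a log2 fold change of 1.97 ± 0.31 (SE, edgeR adjusted p = 0.00324). That call ended without saline conditioned replicate 3 (edgeR adjusted p = 0.056, log2 fold change 1.99) and was kept in 14 of 15 alternatives, with adjusted p from 1.50e-05. Of the genes that fell, the most abundant went from 280.5 ± 52.9 to 139.7 ± 15.3 CPM (SD, n = 3), a log2 fold change of -0.997 ± 0.20 (SE, edgeR adjusted p = 0.0305). The other 2 lay at or under the floor of 3 counts in each LPS library, with 2 counts against 67 and 6 counts against 192 summed over the 3 libraries of each group. Their summed counts per total were 26.7 times lower (exact Poisson interval 7.10 to 225) and 25.5 times lower (11.5 to 70.3). These intervals cover counting error only. A single saline library held 50 of the 67 and 147 of the 192 counts, with group levels of 29.1 ± 21.6 and 82.7 ± 63.8 CPM (SD, n = 3). Without saline conditioned replicate 3 the calls were 2 higher and 0 lower.

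The count of 9 genes in conditioned chicks became 2 without saline conditioned replicate 3 and 4, 4 and 5 without LPS conditioned replicates 1, 2 and 3. It rose to 54, with 28 higher and 26 lower, in a fit on the 6 compared libraries alone, with 8 of the 9 genes among them. With quantile normalization limma called 5 higher and 1 lower, and DESeq2 called 11 higher and 3 lower. With no filter on low counts the balance turned, to 26 higher and 39 lower.

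Whether conditioned chicks responded to LPS with the same genes was examined next. All 6 genes that LPS raised in conditioned chicks were also raised in non-conditioned chicks. The 28 and 9 called genes thus shared 6, where independent lists would share 0.0487 (Fisher's exact test, p = 1.18e-12). That p treats genes as independent, which they are not, and both lists come from one fit with a shared spread. The shared genes numbered 2 without saline conditioned replicate 3, 3 without LPS conditioned replicate 1, 3 without LPS conditioned replicate 2 and 18 with no filter on low counts. Of the 6, 5 had log2 fold changes of 2.22, 1.92, 1.66, 1.54 and 1.005 without conditioning and 2.11, 1.80, 1.52, 1.42 and 0.99 with it. The first of them went from 517 ± 225 to 2432 ± 412 CPM without conditioning (SD, n = 3). Their differences lay between -0.14 and -0.01, and the widest 95% interval of a difference ran from -1.07 to 0.79. These genes were chosen for being called in both states, so a change of some size in both was built into the choice. For ENSGALG00000020316.5, picked for its rise without conditioning, the difference, conditioned minus non-conditioned, was -1.17 (95% interval -2.27 to -0.06), which did not pass the test over all genes (edgeR interaction adjusted p = 0.673).

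Of the 28 genes called without conditioning, 22 had the same sign of change in conditioned chicks. As a set they moved on balance in the same direction there (limma fry, adjusted p = 0.00185), and the 9 genes called with conditioning did so in non-conditioned chicks (limma fry, adjusted p = 9.54e-06). The comparisons share no library, but both sets hold the genes called in both states, and neither set was tested without them. Of the 22 genes called without conditioning only, 16 had the same sign of change in conditioned chicks. Their median change along the direction without conditioning was 1.38 without and 0.23 with conditioning. The 3 genes called with conditioning only had a median of 0.02 without conditioning, along their direction with it. The median change of the 28 genes, taken along its direction without conditioning, was 1.58 without and 0.54 with conditioning, in genes chosen for their change in the former. Over the genes then called, the value with conditioning was 0.16 without saline non-conditioned replicate 1, 1.25 without saline non-conditioned replicate 2, 0.83 without LPS non-conditioned replicate 2 and 0.90 without LPS conditioned replicate 2. ENSGALG00000024449.4 had a log2 fold change of -0.10 ± 0.26 and ENSGALG00000030994.1 of -0.08 ± 0.18 with LPS in conditioned chicks (SE), and neither was called. For ENSGALG00000010915.4 it was -1.06 (95% interval -3.35 to 1.22), also not called. Across the 31 genes called in either comparison the log2 fold changes correlated at a Pearson r of 0.27 (Spearman 0.35), and across all 5170 genes at 0.053, where genes are not independent replicates. Over the genes then called in either comparison, r was 0.59 without LPS non-conditioned replicate 1, 0.49 without saline non-conditioned replicate 3 and 0.41 without LPS conditioned replicate 1. It was lower, at 0.19, without saline conditioned replicate 3.

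**Figure D2:**
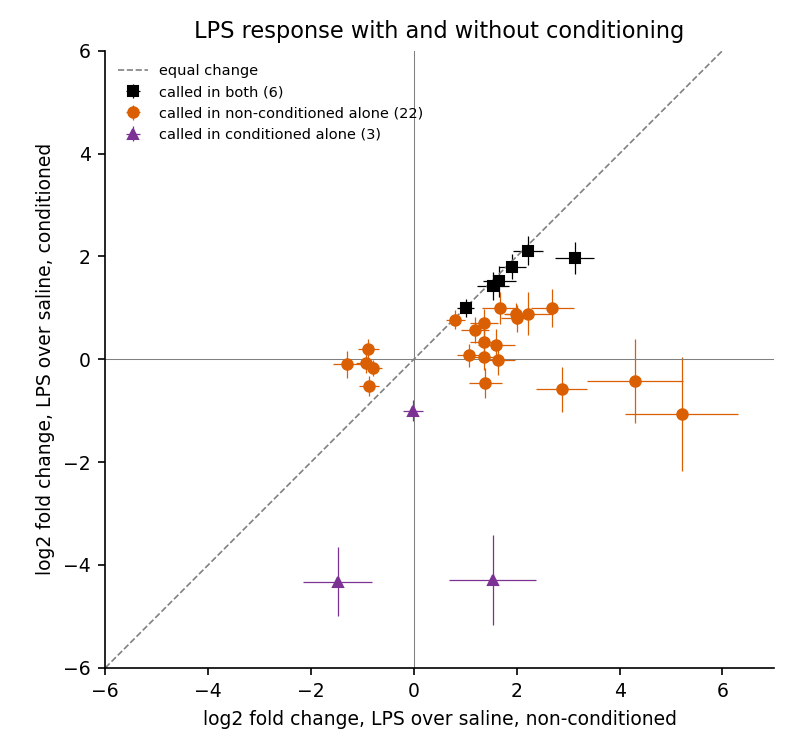
Log2 fold change of LPS over saline in non-conditioned (x axis) and conditioned chicks (y axis) for the 31 genes called in either comparison, with SE bars, and a dashed line for equal change. The 6 genes called in both, a choice that favours a change in both, lie at positive values on both axes, 5 of them close to the dashed line.

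The interaction, which tests whether the LPS response itself differed with conditioning, called 0 genes of 5170 with edgeR (smallest adjusted p = 0.172). At an unadjusted p under 0.05 there were 372 genes where 258.5 are expected by chance, 163 of them with a higher and 209 with a lower value in conditioned chicks. DESeq2 and both limma alternatives also called 0. Among the 28 genes called for LPS without conditioning, the interaction was called in 16 when adjusted over the list alone, which is not independent evidence because the list was chosen on the same libraries, and in 0 over all genes. The gene-wise 95% interval of the interaction had a median half-width of 0.93 on the log2 scale, so for a typical gene a difference within that width was not resolved with these libraries. Leaving out saline non-conditioned replicate 1, saline non-conditioned replicate 2 or LPS non-conditioned replicate 3 gave 5, 1 and 2 called genes.

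**Figure D3:**
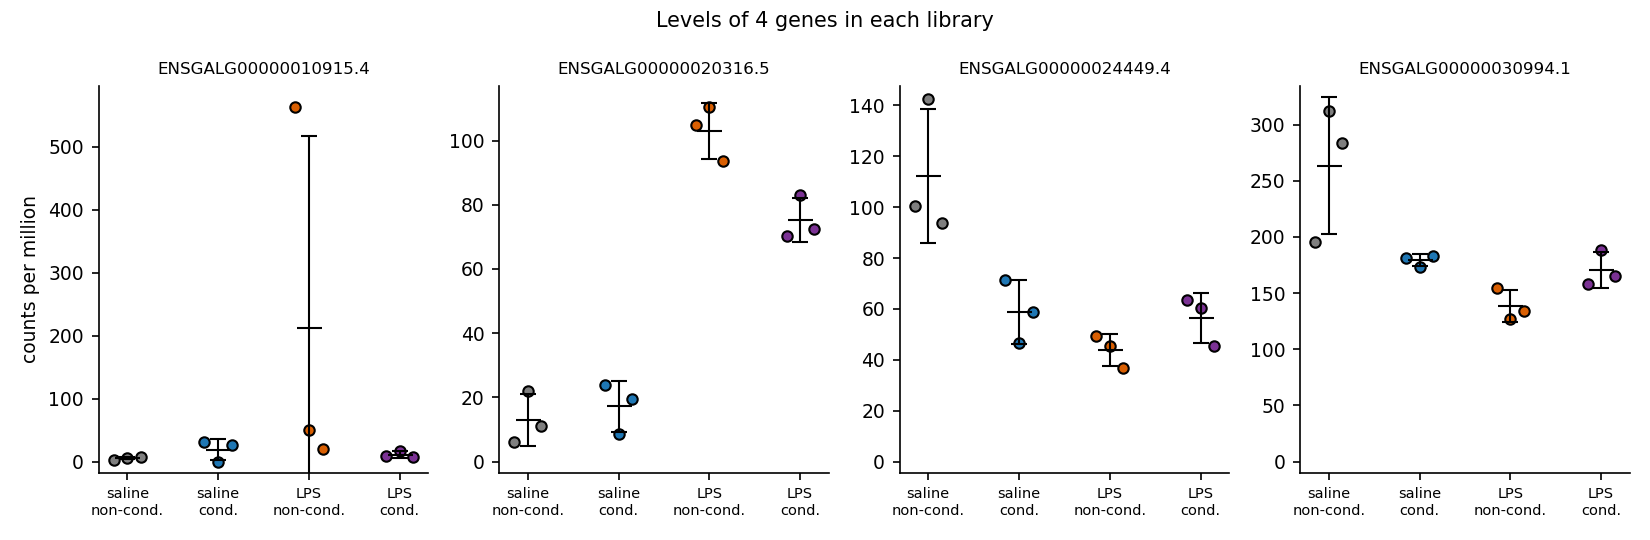
Levels in CPM of the 4 genes named by identifier in each of the 12 libraries, on linear axes that differ between panels, with points for libraries and black lines for the mean and SD of a group. In the panel of ENSGALG00000010915.4 LPS non-conditioned replicate 1 stands at 564 CPM, and the SD line of its group is truncated just below 0.

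In saline-injected chicks the comparison of conditioned with non-conditioned birds asked whether day 3 heat left a difference in microglial expression on day 11. No gene passed with edgeR (0 of 5170, smallest adjusted p = 0.92), and 256 genes had an unadjusted p under 0.05 where 258.5 are expected by chance. DESeq2 and both limma alternatives called 0 genes as well. ENSGALG00000024449.4 was at 58.9 ± 12.5 CPM with conditioning against 112 ± 26.3 without (SD, n = 3), a log2 difference of -0.84 ± 0.25 (SE, edgeR adjusted p = 0.92). ENSGALG00000030994.1 was at 179 ± 5.41 against 264 ± 61.0 CPM (SD, n = 3), a difference of -0.53 ± 0.18 (SE, edgeR adjusted p = 0.92). Both genes were picked for a high level in these same saline non-conditioned libraries. In simulated data with 200 changed genes, 37.2% of 2-fold and 88.8% of 4-fold changes were recovered in this comparison. Each simulated gene had the same spread in all groups. With few changed genes the adjusted threshold is harder to pass, so these shares do not bound what the comparison could detect.

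In LPS-injected chicks, conditioned and non-conditioned birds were compared to ask whether heat conditioning changed the state reached after LPS. No gene passed with edgeR (0 of 5170, smallest adjusted p = 0.157). At an unadjusted p under 0.05 there were 340 genes, 122 higher and 218 lower in conditioned birds, where 258.5 are expected by chance. DESeq2 and limma with quantile normalization each called 1 gene, and limma with library weights called 0. ENSGALG00000010915.4 was at 10.7 ± 5.18 CPM with conditioning and 211 ± 306 CPM without (SD, n = 3), a log2 difference of -4.18 ± 0.88 (SE, edgeR adjusted p = 0.162). It passed without LPS non-conditioned replicates 2 and 3 (edgeR adjusted p = 0.0319 and 0.00587) and with no filter, and the difference was -1.78 without LPS non-conditioned replicate 1, over a range of adjusted p from 1.94e-26 to 0.890. ENSGALG00000020316.5 was at 75.2 ± 6.81 against 103 ± 8.66 CPM (SD, n = 3), a log2 difference of -0.46 ± 0.26 (SE, edgeR adjusted p = 0.818). Both genes were picked for a high level in these same LPS non-conditioned libraries, which favours a lower level with conditioning. A fit on the 6 compared libraries alone called 13 genes, all lower in conditioned birds, and leaving out LPS non-conditioned replicates 1, 2 and 3 gave 1, 1 and 5. Across all 5170 genes the effects of conditioning with saline and with LPS correlated at a Pearson r of -0.11 (Spearman -0.09), where genes are not independent replicates.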

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

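The scaling by the authors' factors was chosen after the data were seen. LPS in non-conditioned chicks changed 28 genes in the report. Quantile normalization in limma gave 10, library weights in limma 11, no filter on low counts 80, an adjusted p under 0.1 gave 52 and a fit on the compared libraries alone 11. Leaving out a library gave 8 to 65. LPS in conditioned chicks changed 9 genes. DESeq2 gave 14, library weights 25, no filter 65 and the compared libraries alone 54, and leaving out a library gave 2 to 8. Conditioning with saline gave 0 genes in every alternative except no filter, with 8. For conditioning with LPS, 0 in the report, DESeq2 gave 1, quantile normalization 1, no filter 64 and the compared libraries alone 13, and leaving out a library gave 0 to 5. For the interaction, 0 in the report, no filter gave 35 and leaving out a library 0 to 5. Of the 80 genes without a filter, 72 were among those tested in the report. Apart from the looser threshold, the cause of these moves was not isolated. For the fit on the compared libraries alone, the shared spread is taken up below as a candidate.

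Of the 28 genes, RLE size factors, the stricter filter and no filter kept 28, DESeq2 27, the compared libraries alone 11, and leaving out saline non-conditioned replicate 2 kept 7. The correlation of the LPS effects ran from 0.053 over all tested genes to 0.63 with quantile normalization. No scaling moved the median log2 fold change of all genes by more than 0.040. ENSGALG00000024449.4, at -0.10 with LPS in conditioned chicks and not called, ranged from -0.20 to 0.035 with a library left out, above 0 without saline conditioned replicate 1 and without LPS conditioned replicate 3 (0.034). Over all comparisons and alternatives of the 4 named genes, 291 values kept direction and side of the threshold, 18 lost a call, 4 gained one and these 2 changed sign. The 291 include results that were not called and stayed so. Calls with LPS in non-conditioned chicks were kept in 8 of 14 alternatives for ENSGALG00000010915.4 and 15 of 15 for ENSGALG00000020316.5. They were kept in 10 of 15 for ENSGALG00000024449.4 and 9 of 15 for ENSGALG00000030994.1. In conditioned chicks the call of ENSGALG00000020316.5 was kept in 14 of 15.

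A pairing of the libraries by replicate number was neither shown nor excluded. Over the 18 pairs of libraries that share a number in different groups, deviations from the group means correlated at -0.11 to 0.13, above 0.1 in 2 pairs. In all, 7 of 12 libraries correlated best with their own number, where some do so by chance. The highest correlation across groups, 0.133, joined different numbers (saline non-conditioned replicate 1 and LPS non-conditioned replicate 2). These values come from the data and not the design. With the replicate number as a block the counts were 25 and 10 for LPS without and with conditioning, 0 and 2 for conditioning with saline and with LPS, and 0 for the interaction.

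The list alternatives were not run, because the reference list used holds no Ensembl identifiers, nor were those planned for normalized values, because counts were deposited. With the observed depth, spread and number of libraries, whose shares were not told apart, 8% to 11.6% of simulated 1.5-fold changes were recovered in the 4 comparisons of groups.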

Other observations

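The averages over both conditioning states or both injections, the depth and permutation tests of the spread, and the test of the shared spread were chosen after the result was seen. Averaged over both conditioning states, LPS changed 38 of 5170 genes (edgeR, adjusted p under 0.05), 28 higher and 10 lower. The median log2 fold change was 1.004 for the genes that rose and -0.86 for those that fell. All 38 had the same sign of change with and without conditioning, in genes picked by the mean of both, and 21 of them were called in neither state alone, 13 higher and 8 lower. One gene that rose is very abundant, at 25279 ± 7015 CPM with saline and 40388 ± 7451 CPM with LPS (SD, n = 6), a log2 fold change of 0.67 ± 0.16 (SE, edgeR adjusted p = 0.0463). Of 100 drawn splits of the injection labels within conditioning states, the real one included, 1 gave as many genes. The highest of the others gave 17. Chance is thus an unlikely source of this count, though no smaller share could be reached with 100 splits and the average was chosen after the result was seen. Other settings gave 18 (a 2-fold minimum) to 109 genes (no filter). The count was 78 without saline non-conditioned replicate 1, 22 without saline non-conditioned replicate 2, 69 without LPS non-conditioned replicate 1, 22 without LPS non-conditioned replicate 2, 19 without LPS conditioned replicate 1 and 24 without LPS conditioned replicate 2. Rises and falls were near even without LPS non-conditioned replicate 1 (34 and 35) and at an adjusted p under 0.1 (42 and 38). With the replicate number as a block they were 31 and 8, and with DESeq2 33 and 20.

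Averaged over both injections, conditioning changed 1 gene, with a log2 difference of -0.80 ± 0.13 (SE, edgeR adjusted p = 0.0207). It stood at 553 ± 54.9 CPM with conditioning against 851 ± 156 without in the saline groups, and at 347 ± 36.0 against 689.6 ± 169.6 in the LPS groups (SD, n = 3). DESeq2 called 2 genes and no filter 37. No gene was called without saline non-conditioned replicate 2, LPS non-conditioned replicate 1 or any single one of the 6 conditioned libraries (edgeR count 0 in each), while 3 and 6 were called without saline non-conditioned replicates 1 and 3. At an unadjusted p under 0.05 there were 241 genes, where 258.5 are expected by chance. Of 100 drawn splits of the conditioning labels, 10 gave as many called genes, with 11 as the highest of the others, so chance cannot be excluded.

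For the counts of the report, the comparisons of 3 against 3 libraries allow 10 splits, too few for a share under 0.05. For LPS in non-conditioned chicks the real split gave 28 genes and the highest other split 1, and 1 of 10 splits gave as many as the real one. For LPS in conditioned chicks the real split gave 9 and another 17, and 2 of 10 gave as many. At an unadjusted p under 0.05 the real splits had 482 and 406 genes, and the highest others 620 and 266, with 2 of the other splits above the real one in non-conditioned chicks. For conditioning with saline and with LPS edgeR gave 0 genes in the real and in every other split, so 10 of 10 gave as many, with 256 and 340 genes at an unadjusted p under 0.05 in the real splits and 424 and 226 in the highest others. For the interaction, 100 of the 100 drawn splits gave at least the 0 genes of the real one, with 6 as the highest of the others. A count of 0 is reached by any split, so the splits say nothing of these 3 counts. The 372 genes of the interaction at an unadjusted p under 0.05 were reached in 5 of the 100, the real one included, with 417 as the highest of the others and a median of 218, so chance cannot be excluded for this count.

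LPS called more genes in non-conditioned than in conditioned chicks, 28 against 9. Library depth is argued against as the cause, since mean totals were lower without conditioning (338271 with saline and 411323 with LPS) than with it (596422 and 474986). With every library thinned to 189180 counts the excess stayed in 20 of 20 thinnings, by a median of 15 genes (10 to 21). Thinning took more counts from the conditioned groups, so it could hardly have removed the excess. A candidate explanation is the single spread estimated for all groups. With each comparison fitted on its own 6 libraries the order turned to 11 against 54, a difference of -43 genes. Those fits also filtered and scaled the 6 libraries anew, so the spread was not told apart from these steps. Library weights in limma gave 11 against 25, while DESeq2 (35 against 14) and quantile limma (10 against 6) kept the order. The non-conditioned count was 65, 8 and 12 without saline replicates 1 and 2 and LPS replicate 2. A weaker LPS response after conditioning cannot be told apart from an equal one, since the signed interaction over the 38 genes picked by their mean effect had a fry p of 0.125, with a median log2 change of 1.13 without and 0.85 with conditioning and 27 of 38 moving less with it. Picking by the mean also leans toward the noisier effect, that of non-conditioned chicks.

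The libraries of conditioned chicks differed less from each other, with a common biological coefficient of variation of 0.159 against 0.248 without conditioning in the saline groups and 0.121 against 0.183 in the LPS groups. Depth is argued against, since after thinning to equal depth the ratio of non-conditioned to conditioned spread was never below 1.41. Chance differences between exchangeable libraries cannot be told apart from a wider spread, since the measures differ: a mean ratio as far from 1 as the observed 1.47 came up in a median share of 0.065 (0.045 to 0.08 over 20 thinnings) of the 400 relabellings within injections (exact permutation, 2-sided, smallest possible share 0.005), with 1.61 as the highest of the others, against 0.02 (0.01 to 0.05) for the median SD over genes. The ratio of that SD was never below 1.06. It was taken from log2 CPM without TMM scaling, where a few abundant genes can shift the level of all others. A few variable genes as the whole cause are therefore not excluded, and the share of 0.02 has the same limit. A single library that stands apart in each non-conditioned group cannot be told apart from a wider spread either, since the narrowest non-conditioned pair spread 1.14 times as much as the widest conditioned pair with saline and 0.884 times as much with LPS, and an effect of conditioning, sorting or pooling on variation stays open beside it, untested.

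The gene with the widest range over libraries, not called by edgeR in the 5 comparisons of the report, stood at 5913 CPM in saline non-conditioned replicate 2 and 4538 CPM in LPS non-conditioned replicate 1. It stood at 42.7 and 35.7 CPM in saline non-conditioned replicates 1 and 3, and between 36.2 and 49.8 CPM in the 3 LPS conditioned libraries. The saline conditioned libraries stood at 134, 266 and 609.8 CPM, and LPS non-conditioned replicates 2 and 3 at 300.9 and 906 CPM.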
